A study of Homo sapiens with 9 samples.

How the data were processed

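The study profiled 2 histone marks, H3K4me3 and H3K4me1, by ChIP-seq in MIA PaCa-2 cells, an established human pancreatic carcinoma line. Per the labels, cells received 50 nM of scramble siRNA or of 1 of 2 siRNAs against KMT2D, a histone H3 lysine 4 methyltransferase. They were transfected again 24 h later, and chromatin was isolated 24 h after that. Chromatin immunoprecipitation used an enzymatic ChIP kit, libraries were made with a ChIP-seq library kit, and 2% input was sequenced for each siRNA, per the labels' protocols. The 9 samples are 6 IP libraries and 3 inputs, with 1 library per group. The siRNAs are called KMT2D siRNA 1 and KMT2D siRNA 2 after the sample descriptions. The sample titles read siMLL1 for siRNA 1 and siMLL3 for siRNA 2, while the description of the siRNA 2 input reads siMLL2. MLL1 and MLL3 are also names of other genes, KMT2A and KMT2C, so that KMT2D is the target of both siRNAs rests on the descriptions of the IP samples.

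Each IP library came with 1 deposited list of annotated regions, and lists were not pooled over libraries. BWA 0.7.9a, Picard 1.115, SAMtools 0.1.19 and HOMER 4.7 with build hg19 are named in the submitters' processing notes, without their roles. Per the file headers, the regions were annotated with HOMER annotatePeaks.pl on hg19, and the IP and input tags in each region were counted. The deposited IP and input values are signal in tags per 10 M tags of the library, per the file headers. Each deposited peak score is the same IP signal to within 0.05 per 10 M. All values were whole tags within 0.1 when scaled back by the library's total, so the number of tags behind each value is known. The settings of the peak finder are not given in the sources used here. In the values, no region was under 500 bp and none had less than 4 times as many IP as input tags per 10 M. The score is the authors' value for a region of 1 library and was used to rank or filter peaks within a list. Mean scores and IP tags per 10 M given for several libraries describe each library and are not adjusted for its enrichment, so they do not show a change in the mark.

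Total tags of the IP libraries, per the file headers, were 21.8 M (scramble), 33.4 M (siRNA 1) and 42.0 M (siRNA 2) for H3K4me3, and 21.3, 26.9 and 29.2 M for H3K4me1 in the same order. The inputs held 30.4, 22.6 and 36.8 M tags. The median peak held between 150 and 249 IP tags for H3K4me3, but only between 21 and 28 for H3K4me1, against 3 to 7 input tags. H3K4me1 calls thus rest on few tags. In the siRNA 1 library 9.33% of H3K4me1 peaks had 0 or 1 input tags, compared with 2.19% for scramble and 1.08% for siRNA 2.

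Lists were compared by position. A peak counted as shared where at least 1 bp overlapped a peak of the other list; only peaks on chromosomes 1 to 22, X and Y were used. Scramble peaks without overlap in a siRNA library are called absent from it, and peaks of a siRNA library without overlap in the scramble list are called gained, as terms for these lists only. Promoter peaks had their centre within 2500 bp of the nearest annotated transcription start site (TSS), by the distance in the files. A gene was called marked by H3K4me3 where a peak had it as its nearest TSS within 2500 bp. For H3K4me1, the length of all peaks with the gene as nearest TSS was summed. Log2 ratios of length used a pseudocount of 500 bp. Because a peak's centre moves with its ends, and with it the nearest TSS, TSS positions were also recovered from the region centres and signed distances in the files. This gave 19877 of the 21659 promoters named as nearest to a peak in any of the 6 lists. A gene that no peak names thus has no recovered TSS. The length of H3K4me3 peaks within 2500 bp on either side of these TSSs was used as an added alternative. Gene names are those in the files, with older symbols matched to current ones through an NCBI table of the GRCh38.p14 assembly, of which no coordinates were used. Coordinates are hg19 as the files give them.

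With 1 library per group there is no test across replicates and no p-value. Shares have exact Clopper-Pearson 95% intervals, and ratios of counts have 95% Poisson intervals. Intervals of ratios of covered length were taken from the numbers of peaks alone, so they leave out the spread of peak widths. Differences of shares have Newcombe 95% intervals. The intervals cover counting error only, and neighbouring peaks are not independent. Peaks absent from both siRNA libraries were set against independent lists and against chance within 50 strata of scramble score. Since both siRNA libraries are compared with the same scramble library, which cannot be split, each siRNA library was also taken as the reference in its place. Overlap by position alone was measured with 100 random shifts of the scramble peaks along their chromosomes. For 17 gene lists with 321 genes in all, the median log2 ratio of length was placed among 10000 random lists of the same size, matched on scramble score or length in 10 strata, for lists with at least 5 genes seen. The percentile describes these libraries and is not a test of the siRNA. The lists were H3K4 methyltransferases and demethylases, glucose uptake and glycolysis, lipid synthesis, TCA cycle and respiratory chain, pancreatic cancer drivers, TGF-beta and mesenchymal genes, epithelial and foregut genes, AP-1, YAP/TEAD and RUNX regulators, cell cycle, interferon response, stress response, widely expressed controls, developmental transcription factors, and markers of acinar, islet, blood, and fibroblast or endothelial cells.

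Genes were named by a rule set before the data were examined, as were the groups, the main comparisons and most other settings. It takes KMT2D, then for each mark the 10 protein-coding genes with the highest scramble score among peaks absent from both siRNA libraries, and the 10 with the highest siRNA 1 score among gained peaks that overlapped a siRNA 2 peak. For H3K4me3 only promoter peaks entered; the rule sets this for absent peaks, and it was applied to gained peaks too. Within each list it takes up to 4 genes whose call differed from scramble in the same direction in both siRNA libraries, or else up to 2 with the largest mean log2 length ratio of the same sign. Results for a few genes that the rule takes are not reported here. Other genes named below were chosen after their values were seen.

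The overlap, strata, list and TSS steps were tested on simulated data first. All 200 peaks removed from copies of each scramble list and all 200 peaks added were recovered, with no others called. Losses drawn independently gave ratios to score-matched chance of 1.00 (H3K4me3, 17741 peaks) and 0.996 (H3K4me1, 30811 peaks). With 500 joint losses added these ratios were 1.05 and 1.03. The independent losses depended on score alone, so their ratio near 1 was set by the design. For H3K4me3 they gave 3770 peaks lost in both, against 1235 in the data. Differences between peaks of similar score, such as in input, were not simulated. A list shifted by -1 on the log2 scale was found in 20 of 20 simulated H3K4me1 sets of 10448 genes, in which 1 of 240 unshifted lists passed in both libraries. These sets held only genes with H3K4me1 in scramble, with noise drawn independently for each siRNA library. In the data both ratios share 1 scramble library, so this rate need not hold there. All 2883 TSSs recovered from simulated regions lay at their true position. Other settings tried were a required overlap of at least 50% of the peak, a gap of up to 1000 bp, stricter lists by score, lists of equal number, merging of peaks within 1000 bp, promoter limits of 1000 and 5000 bp, a limit of 50000 bp for H3K4me1, a pseudocount of 100 bp, and strata of score and width. Settings added after the data were seen are named with their values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.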

Results

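ChIP-seq peak lists of H3K4me3, a mark of active promoters, and H3K4me1, a mark of enhancers and promoter flanks, were compared between MIA PaCa-2 pancreatic cancer cells treated with scramble siRNA and cells treated with either of 2 siRNAs against KMT2D. KMT2D (also known as MLL2 or MLL4) is a methyltransferase known chiefly for H3K4me1 at enhancers. The comparison asks which marked regions differ when it is targeted. The titles of the siRNA 2 samples read siMLL3, and MLL3 is a name of the related gene KMT2C, so the target of siRNA 2 rests on the sample descriptions. The 6 IP libraries held 21.3 to 42.0 M tags, with 1 library for each mark and siRNA and 1 input for each siRNA. All values are thus single measurements without replicate error, and the intervals given are exact Clopper-Pearson 95% intervals, Poisson intervals for ratios or Newcombe intervals for differences of shares, that cover counting error only.

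The KMT2D locus itself carried both marks in all 3 conditions. The H3K4me3 peak upstream of KMT2D spanned chr12:49450522-49455503 (hg19) in the scramble library, with 456 IP tags (209 per 10 M) against 43 input tags. The siRNA 1 peak spanned 49449815-49455732, with 870 IP tags (260.2 per 10 M) against 33, and the siRNA 2 peak 49450277-49455584, with 673 (160.1 per 10 M) against 37. Per 10 M tags, IP was 14.7, 17.8 and 15.9 times input in scramble, siRNA 1 and siRNA 2. The files annotate these peaks as intergenic, with centres at -3905, -3666 and -3823 bp from the KMT2D TSS, negative values lying upstream. The H3K4me1 peak at the locus was 732 bp wide in the scramble library, 1324 bp with siRNA 1 and 1655 bp with siRNA 2. An siRNA acts on the transcript, so these peaks do not measure the knockdown, and no RNA or protein level was analysed here.

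By TSS windows, an added rule, genes with a H3K4me3 peak near a TSS in scramble had one in both KMT2D siRNA libraries with few exceptions. A gene counted as marked where the window of any of its recovered TSSs held part of a peak, also one assigned to a neighbouring gene. Loss at 1 of several promoters of a gene is thus not seen. Within 2500 bp of recovered TSSs, 12493 genes had a H3K4me3 peak in the scramble library, 12600 with siRNA 1 and 12490 with siRNA 2. Of the 12679 genes with a peak in any library, 12345 (97.4%) had one in all 3. Only 25 genes had a peak in the scramble library alone, and 91 had one in both siRNA libraries and not in scramble. For comparison, 69 genes were marked in the siRNA 1 library alone and 26 in the siRNA 2 library alone, while 28 were unmarked only with siRNA 1 and 95 only with siRNA 2. Independent losses of 53 and 120 genes would share 0.509 genes, but this expectation was not matched on score. For H3K4me3 peaks, matching on score raised the expected number absent from both from 196 to 1001. As 26 genes were marked with siRNA 2 alone, a number like the 25 was not particular to scramble. When genes were assigned by the nearest TSS of the peak centre, as planned, 11126, 11230 and 11154 genes were marked, 251 in scramble only and 278 in both siRNA libraries only. By this rule 10338 of the 12019 genes marked in any library (86.0%) were marked in all 3. Independent losses of 547 and 492 genes would share 24.2, again without matching on score. For comparison, 373 genes were marked with siRNA 1 alone and 242 with siRNA 2 alone. A limit of 1000 bp gave 409 genes in scramble only and 422 in both siRNA libraries only. By TSS windows these numbers were far lower, as given above. AURKA, MCM7, SLC16A1 and RBM10 differed by the centre rule, yet their TSS windows held 3457 to 5000 bp of H3K4me3 in every library.

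Promoter H3K4me3 peaks seen with both siRNAs but not in scramble included those at MMP24, a membrane-type matrix metalloproteinase (chr20:33812829-33816415, 157 IP tags in the siRNA 1 library), and at CADM4, a cell adhesion molecule (chr19:44142009-44145009, intron 1, 131 IP tags). EPHB3, an ephrin receptor, had 118 IP tags with siRNA 1 and 99 with siRNA 2 at its promoter (35.3 and 23.6 per 10 M). IRF9, the DNA-binding part of the interferon-activated factor ISGF3, had 95 and 43 IP tags (28.4 and 10.2 per 10 M) in a peak that began at chr14:24630284 with siRNA 1 and at 24630292 with siRNA 2. C3orf55, ASCL5 and CDH12 likewise had no H3K4me3 peak called in their TSS windows in scramble. Tags are known for called regions only, so weaker H3K4me3 there was not measured. Some siRNA 2 calls lay close to the least IP over input seen in the lists, 4 times. They were 4.11 times at MMP24 and 4.06 times at CDH12, where the peak was 500 bp wide. At R3HDM4 and MAFG, where peaks were gained too, the scramble library had other H3K4me3 in the window, 1612 and 3412 bp. At the remaining genes from EPHB3 to MAFG and at CADM4, IP over input with siRNA 2 was 5.11 (EPHB3) to 9.39 (IRF9). Per 10 M, the gained peaks of the genes from MMP24 to MAFG, 1 per gene, had 26.9 (MAFG) to 46.95 (MMP24) IP tags with siRNA 1. With siRNA 2 they had 8.80 (CDH12) to 33.55 (CADM4). RNF43, a ubiquitin ligase that removes Wnt receptors from the cell surface, had 664 bp of promoter H3K4me3 with siRNA 1 and 500 bp with siRNA 2, against no called peak in scramble. In the opposite direction, the strongest promoter peaks of protein-coding genes present in scramble alone held few tags. Scramble was also the H3K4me3 library with the fewest tags (21.8 M). The WNT2B peak at chr1:113008416-113009490 had 44 IP tags (20.1 per 10 M) against 14 input tags. Peaks at ZNF451, RANBP3L, EGFLAM, ZNF219, LPPR3, CCZ1, PPP1R3D, AHCY and KRT13 had 25 to 28 (11.4 to 12.8 per 10 M). Per 10 M these values lie within the siRNA 2 range of the gained peaks. Among the genes with these scramble peaks, only RANBP3L and KRT13, a keratin of stratified epithelia, had no H3K4me3 peak in the TSS window with either siRNA. Their windows held 727 and 804 bp in scramble. In the windows of the other 8 genes, H3K4me3 of at least 673 bp was left with each siRNA, the least at CCZ1 with siRNA 2.

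**Figure D1:**
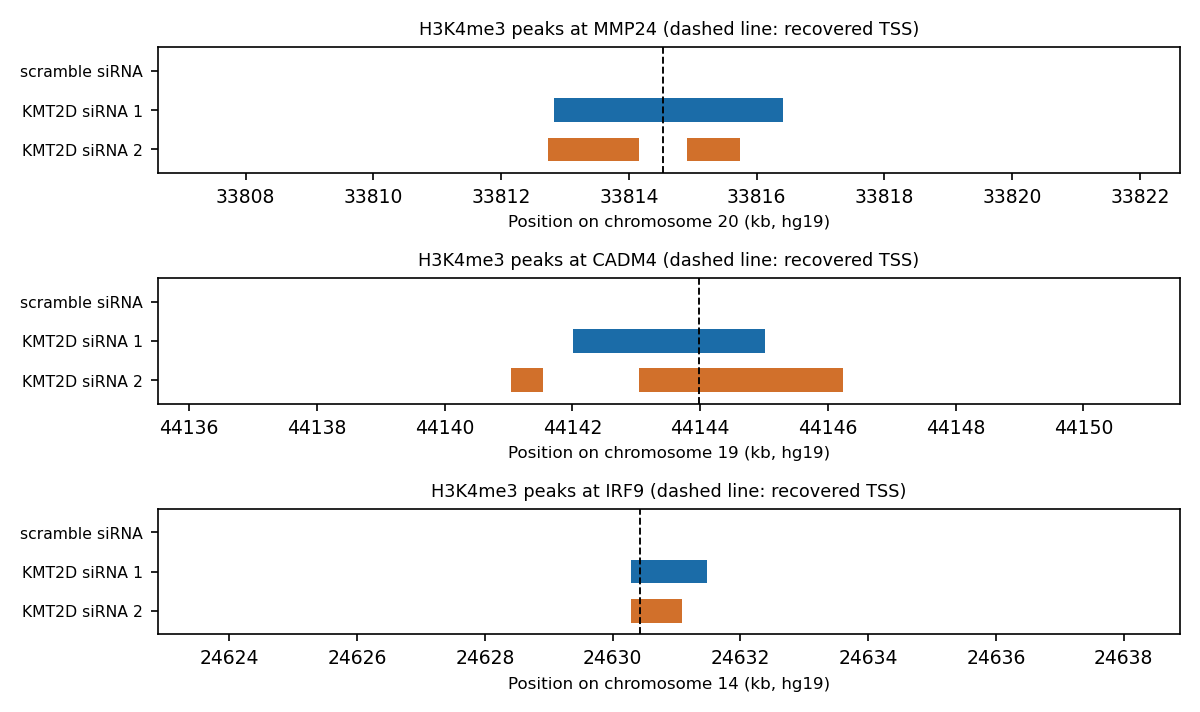
Positions of H3K4me3 peaks (bars) in the scramble (top line of each panel, without peaks), KMT2D siRNA 1 (blue) and KMT2D siRNA 2 (orange) libraries around MMP24, CADM4 and IRF9, with position in kb of hg19 on the x axis and the recovered TSS as a dashed line. Within 2500 bp of each of these TSSs both siRNA libraries have peaks and scramble has none.

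Peak lists of H3K4me3 differed mainly among low-scoring peaks, which were also narrower. The lists held 17741 peaks for scramble, 19165 for siRNA 1 and 16889 for siRNA 2, covering 39.5, 48.8 and 39.2 Mb, with mean widths of 2226, 2547 and 2323 bp and mean scores of 83.3, 87.8 and 68.0 tags per 10 M. Of the scramble peaks, 8.44% (1498, interval 8.04 to 8.86%) were absent from the siRNA 1 library and 13.1% (2316, 12.6 to 13.6%) from the siRNA 2 library. In the lowest score decile 59.2% and 77.8% were absent. In the higher-scoring 50% of scramble peaks only 1 and 5 of 8870 peaks were. Median width was 500 bp in the lowest decile and 4592 bp in the highest, and a wider peak meets the 1 bp overlap more easily. Gained peaks made up 18.0% (3452) of the siRNA 1 list and 8.66% (1463) of the siRNA 2 list. Of those in the siRNA 1 list, 545 overlapped a siRNA 2 peak. For comparison, 263 scramble peaks were absent with siRNA 1 only and 1081 with siRNA 2 only. Peaks missing from 1 library alone were thus not particular to scramble. With lists of equal number, gained peaks made up 9.37% of the siRNA 1 list. At genes marked in all libraries the H3K4me3 in the TSS window was longer with siRNA 1 at 80.2% of genes (median log2 ratio 0.19) and with siRNA 2 at 54.3% (median 0.02). Chance overlap by position was 3.44% and 2.99%, compared with observed overlaps of 91.6% and 86.9%.

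H3K4me1 lists shared far fewer peaks. They held 30811 peaks in the scramble library, 36888 with siRNA 1 and 28538 with siRNA 2, covering 31.6, 40.2 and 32.9 Mb, with mean widths of 1026, 1090 and 1154 bp and mean scores of 17.2, 16.4 and 18.2. Of the scramble peaks, 48.8% (15027, interval 48.2 to 49.3%) were absent from the siRNA 1 library and 53.5% (16492, 52.97 to 54.08%) from the siRNA 2 library. Chance overlap was 2.93% and 2.32%. Most of the highest-scoring peaks were shared: in the highest decile 6.62% and 6.10% were absent, compared with 75.5% and 81.9% in the lowest. Median width also differed, at 2888 bp in the highest decile and 500 bp in the lowest, so score and width are not separated. In the higher-scoring 50% of scramble peaks 28.96% and 33.3% were absent. Broad H3K4me1 regions at CD44, a cell surface receptor for hyaluronan, and at WWTR1, which encodes the YAP-related coactivator TAZ, were among the 5 strongest peaks of every library. Gained peaks made up 59.0% (21764) of the siRNA 1 list and 51.8% (14788) of the siRNA 2 list. Of those in the siRNA 1 list, 5489 overlapped a siRNA 2 peak. For comparison, 3746 scramble peaks were absent with siRNA 1 only and 5211 with siRNA 2 only. With the 28538 highest-scoring peaks of each list, 50.2% and 51.2% of scramble peaks were absent from the siRNA 1 and siRNA 2 lists, and 49.5% of siRNA 1 peaks were absent from the siRNA 2 list. The libraries of the 2 KMT2D siRNAs thus differed from each other nearly as much as from scramble.

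**Figure D2:**
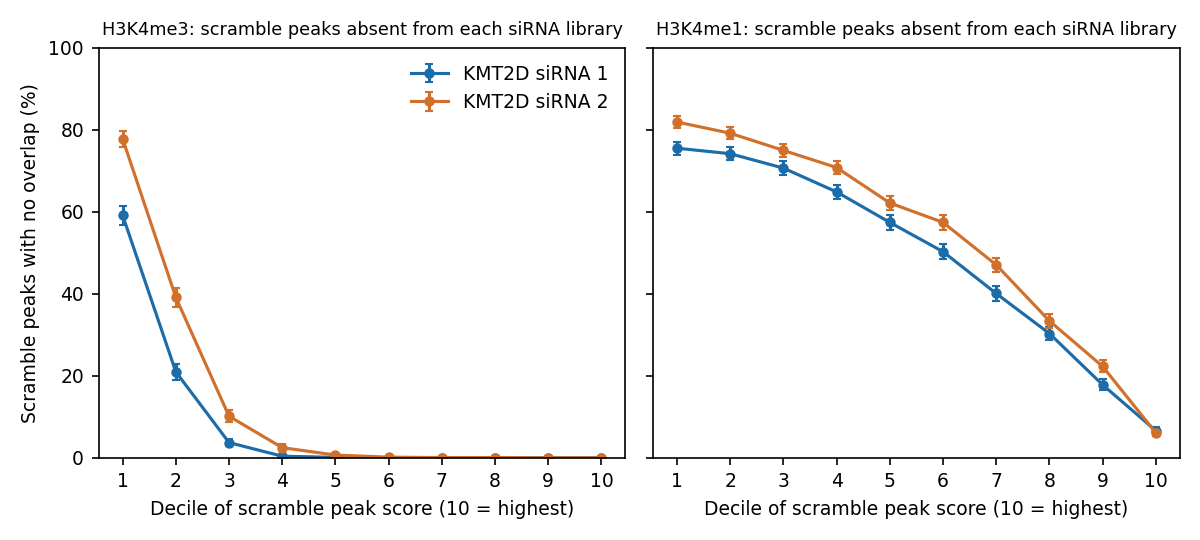
Share of scramble peaks (y axis, %) with no overlap in the KMT2D siRNA 1 (blue) or siRNA 2 (orange) library, by decile of scramble peak score (x axis, 10 is highest), for H3K4me3 (left) and H3K4me1 (right). Points are single libraries and bars are exact 95% binomial intervals. The share falls with score in both marks. It goes from 59.2% and 77.8% to 0% for H3K4me3 and from 75.5% and 81.9% to 6.62% and 6.10% for H3K4me1. Median peak width is also larger in the highest decile than in the lowest, so score and width are not separated.

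Among the strongest H3K4me1 peaks seen with both siRNAs and not in scramble was one in intron 1 of TP63, a p53-family factor of squamous and basal cells, at chr3:189511545-189518512 in the siRNA 1 library (343 IP tags against 56 input tags) and 189513211-189517667 in the siRNA 2 library (264 against 67). It was 1 of many H3K4me1 peaks assigned to TP63, which summed to 84441 bp in scramble, 140562 bp with siRNA 1 and 81828 bp with siRNA 2. At LOC389602 the peaks lay at the promoter, with centres -1282 bp (siRNA 1, annotated as intergenic) and 453 bp (siRNA 2, exon 1) from the TSS, and the TSS window held 0, 5000 and 4693 bp of H3K4me1 in scramble, siRNA 1 and siRNA 2. The MCM3AP peaks, in intron 2, were centred 2121 and 1879 bp from its TSS. Others lay in introns of CYB5B, LARP1, SMS and TNPO1, or in intergenic sequence far from the TSSs of PDE10A and BDH1. At these loci the siRNA 1 peaks held 212 to 343 IP tags. The siRNA 2 peaks held 39 (TNPO1) to 475 (LARP1), with 51 at CYB5B and 70 at SMS. Per 10 M, IP was 4.21 (CYB5B) to 6.14 (TNPO1) times input with siRNA 1, where the median of all H3K4me1 peaks was 5.66. With siRNA 2 it was 4.03 (CYB5B) to 7.69 (MCM3AP), against a median of 5.15. At TP63 it was 5.14 and 4.98 times. The least seen in the lists was 4 times. The scramble peaks absent from both siRNA libraries at the 10 protein-coding genes taken by the rule held 89 to 109 IP tags. The strongest of these was in intron 1 of N4BP1 (chr16:48639144-48641864, 109 IP tags against 35 input tags, 51.1 IP tags per 10 M). The others were assigned to RRAS2, TRPV2, ASAP2, SH3TC2, GALNS, NSA2, SGK1, PSD4 and FA2H. IP in these 10 peaks was 4.32 (NSA2) to 5.58 (SH3TC2) times input, against a median of 5.30 over all scramble H3K4me1 peaks. A high score, which sums tags over the region, thus did not go with a high IP over input here. Over all peaks absent from both siRNA libraries, the highest score was 54.4 per 10 M. The summed H3K4me1 assigned to SGK1, a serum and glucocorticoid regulated kinase, was 44326 bp in scramble, 59017 bp with siRNA 1 and 46504 bp with siRNA 2, while TRPV2, a cation channel, had 3718, 500 and 0 bp and GALNS 3021, 0 and 0 bp. The TSS window of GALNS held 2395, 0 and 955 bp, so H3K4me1 was still called near it with siRNA 2.

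Distal H3K4me1 peaks were absent more often than promoter peaks under the planned definition. Of 22805 scramble peaks over 2500 bp from a TSS, 51.7% (51.05 to 52.35%) were absent with siRNA 1 and 58.0% (57.3 to 58.6%) with siRNA 2. Of 8006 promoter peaks, 40.4% (39.4 to 41.5%) and 40.8% (39.7 to 41.9%) were. The differences were 11.3 (10.01 to 12.5) and 17.2 (15.9 to 18.4) percentage points. Absence did not rise steadily with distance. Of peaks 5000 to 50000 bp from a TSS 55.5% and 62.0% were absent, but of those beyond 50000 bp only 46.1% and 52.8%. Peaks that overlapped scramble H3K4me3 were absent in 29.3% and 28.9% of cases, compared with 57.8% and 65.0% of peaks without it, but their median score was also higher (13.1 against 8.91). With a promoter limit of 1000 bp the difference was -3.52 points for siRNA 1 and 0.015 points for siRNA 2, since peaks 1000 to 2500 bp from a TSS were absent least often (35.9% with each siRNA) and those within 1000 bp in 52.0% and 53.5% of cases. Among the higher-scoring 50% of scramble peaks the difference was 3.56 and 7.88 points, and with the higher-scoring 50% of every list it was 1.77 and 4.81 points. Promoter peaks made up 26.0% of the scramble H3K4me1 list, 26.2% of the siRNA 1 list and 32.9% of the siRNA 2 list.

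Most genes of the metabolism, cell cycle and stress lists with a recovered TSS had H3K4me3 near it in all 3 libraries, as did 12345 of all 14929 genes with a recovered TSS. A TSS could be recovered only where a peak of either mark in these same lists named it. Genes without such a peak are left out of these counts, so high shares are partly set by this. By TSS windows, all 23 glucose uptake and glycolysis genes with a recovered TSS were marked in every library, as were all 20 TCA cycle and respiratory chain genes, 18 H3K4 methyltransferase and demethylase genes, 20 AP-1, YAP/TEAD and RUNX regulators, 14 stress response genes and 18 widely expressed control genes. SLC2A3, which encodes the glucose transporter GLUT3, had 2944, 3814 and 2709 bp of H3K4me3 in its window in the scramble, siRNA 1 and siRNA 2 libraries, and SLC2A1 had 3087, 3245 and 3327 bp. Of the lipid synthesis, uptake and storage genes, 24 of 25 were marked in all libraries. PPARG, a regulator of fat storage, had 2183, 1637 and 1183 bp, and FADS2, a fatty acid desaturase, 3323, 4166 and 3402 bp. In all libraries 18 of 19 cell cycle genes, 14 of 15 pancreatic cancer drivers, 13 of 14 interferon response genes, 12 of 15 TGF-beta and mesenchymal genes, 11 of 15 epithelial and foregut genes and 8 of 16 developmental transcription factors were marked. CCND2 had a window without a peak with siRNA 1 only, and HOXA9 had 500, 43 and 0 bp. Windows with a recovered TSS were found for 0 acinar and 0 blood cell markers, 2 islet markers (1 marked in all libraries) and 8 fibroblast and endothelial markers (4 marked in all libraries).

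No list had a median promoter H3K4me3 length ratio outside the central 95% of matched random lists in both siRNA libraries, among 13 lists with enough genes. The glycolysis list lay at percentiles 22.8 and 5.75 (median log2 ratios 0.13 and -0.08) for siRNA 1 and siRNA 2, the lipid list at 61.2 and 8.01, the TCA list at 72.9 and 30.3, and the cancer driver list at 94.2 and 92.5. For the interferon response list, percentile 1.08 with siRNA 1 (median 0.02 against 0.22 in random lists) stood against 50.2 with siRNA 2. Percentiles for siRNA 1 and siRNA 2 were 30.0 and 68.1 for the H3K4 enzymes, 64.0 and 37.7 for TGF-beta and mesenchymal genes, 12.6 and 53.4 for epithelial and foregut genes, and 65.3 and 90.0 for AP-1, YAP/TEAD and RUNX regulators. They were 63.4 and 62.9 for the cell cycle, 53.2 and 19.3 for stress genes, 25.8 and 75.2 for control genes, and 53.9 and 65.0 for developmental factors.

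H3K4me1 was shorter in both siRNA libraries at epithelial and foregut genes, the only 1 of 14 lists outside the central 95% of random lists with both siRNAs. The 12 genes with any H3K4me1 peak had a median log2 length ratio of -0.52 with siRNA 1 (percentile 1.74) and -0.92 with siRNA 2 (percentile 0.58), against 0.07 and -0.12 in random lists. H3K4me1 was seen at 12, 11 and 7 of them in the scramble, siRNA 1 and siRNA 2 libraries. ELF3, an epithelial ETS factor, had 3384, 1738 and 1305 bp, the keratin gene KRT7 1172, 665 and 0 bp, KRT18 4166, 2778 and 3224 bp, and the tight junction gene CLDN7 1000, 500 and 0 bp. CLDN4 and KRT19 were shorter with siRNA 1 only (8417, 7161 and 10532 bp, and 4160, 2440 and 4333 bp), whereas CDH1, SOX9 and MUC1 were shorter with siRNA 2 only. The list no longer lay outside that range in both libraries with only the higher-scoring 50% of peaks (9 genes, medians -0.50 and -0.33, siRNA 2 percentile 20.8), with only peaks over or only peaks within 2500 bp of the TSS (siRNA 2 percentiles 20.2 and 16.5), or with peaks within 50000 bp of the TSS. In the last case the medians, -0.52 and -0.86, were nearly those of all peaks, at percentiles 3.09 and 1.82.

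**Figure D3:**
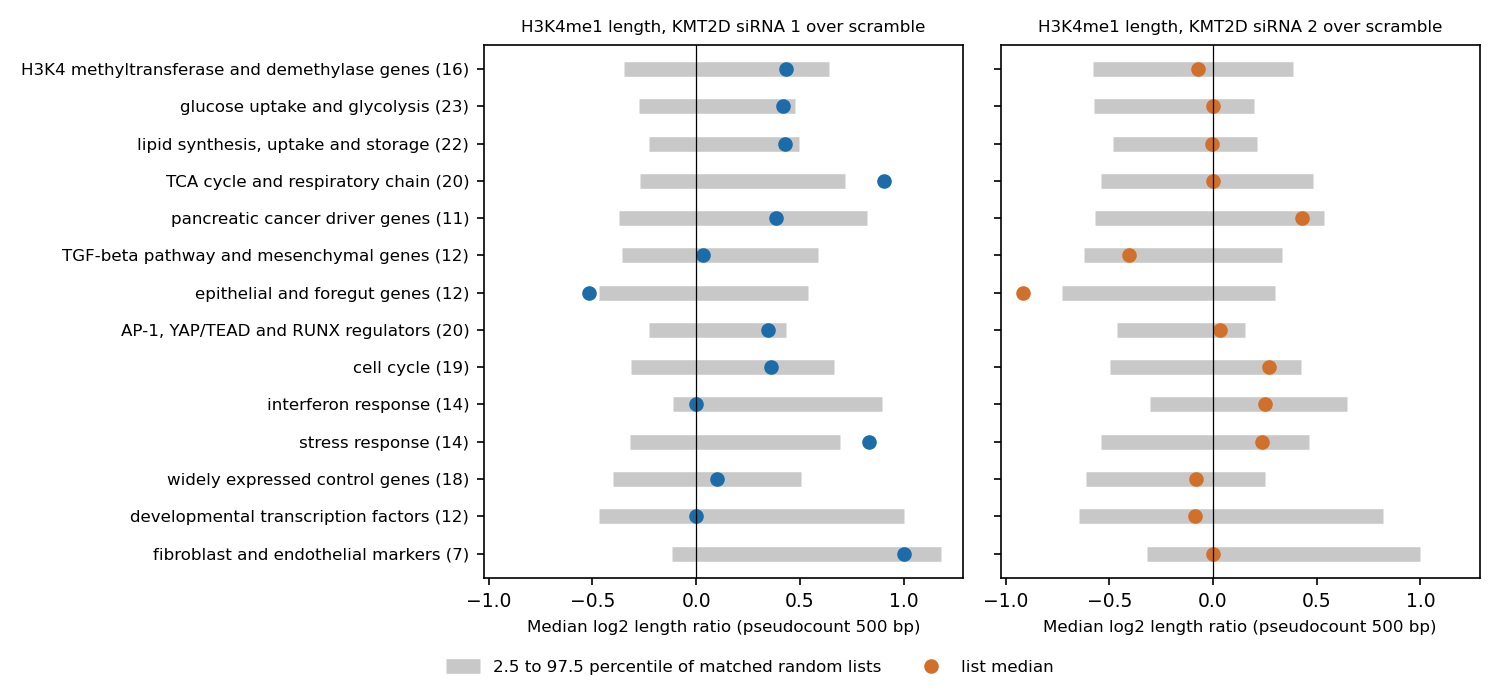
Median log2 ratio of H3K4me1 length (x axis) of each gene list, KMT2D siRNA 1 over scramble (left, blue) and siRNA 2 over scramble (right, orange), with the number of genes seen in brackets. Grey bars span the central 95% of 10000 matched random lists. Epithelial and foregut genes lie below the bar in both panels (-0.52 and -0.92), and TCA and stress genes above it with siRNA 1 only.

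Assigned H3K4me1 is the length of peaks with the gene as nearest TSS, so a gene without it can still have H3K4me1 nearby. At the other lists the 2 siRNAs did not leave the range of random lists together. TCA cycle genes had a median H3K4me1 ratio of 0.91 with siRNA 1 (percentile 99.6) and 0.00 with siRNA 2 (percentile 45.3). CS and PDHA1, which encode citrate synthase and a subunit of pyruvate dehydrogenase, were longer in both libraries (500, 1983 and 2942 bp, and 500, 2914 and 2417 bp), and NDUFS1 had assigned H3K4me1 only with the siRNAs (1000 and 669 bp). Stress response genes lay at percentiles 99.4 and 87.7, with ATF4 and ASNS marked only with the siRNAs and CHAC1 only in scramble. Glycolysis genes lay at percentiles 95.2 and 74.3. PGK1 had 649, 2284 and 3565 bp and PFKP 4218, 500 and 2990 bp, while SLC2A3 had 4175, 6048 and 1792 bp. The lipid list lay at 94.9 and 65.2, with ACSL1 at 500, 2515 and 1343 bp and DGAT1 at 1000, 1620 and 2998 bp. Cancer drivers lay at 73.1 and 95.1, with GNAS at 0, 1849 and 2276 bp. For TGF-beta and mesenchymal genes the percentiles were 36.5 and 9.17. TWIST1 had H3K4me1 only with the siRNAs, and FN1 and SPARC only in scramble. Percentiles were 88.1 and 42.3 for the H3K4 enzymes, 92.7 and 86.7 for AP-1, YAP/TEAD and RUNX regulators, and 77.1 and 92.2 for the cell cycle, where CCND1 was marked only with the siRNAs and CCNA2 only in scramble. They were 11.7 and 78.0 for interferon genes, 54.8 and 59.6 for control genes, 18.98 and 15.9 for developmental factors, and 88.3 and 27.6 for fibroblast and endothelial markers. Of the control genes, B2M and RPLP0 had H3K4me1 peaks (626 and 825 bp) only in scramble. For acinar, islet and blood cell markers 0, 2 and 3 genes had any H3K4me1 peak.

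Scramble peaks absent with siRNA 1 were often also absent with siRNA 2. For H3K4me3, 1235 peaks (6.96%, interval 6.59 to 7.35%) were absent from both, 1.23 times (1.17 to 1.30) the number given by chance among peaks of similar score and far above the 196 of independent lists. For H3K4me1, 11281 peaks (36.6%, 36.1 to 37.2%) were absent from both, compared with 8043 for independent lists, and 1.15 times (1.13 to 1.17) score-matched chance. With the siRNA 1 or siRNA 2 library as the reference instead of scramble, the score-matched ratios were 1.111 and 1.311 for H3K4me3 and 1.08 and 1.09 for H3K4me1. With lists of equal number and scramble, siRNA 1 and siRNA 2 as the reference in turn, they were 1.321, 1.264 and 1.240 for H3K4me3 and 1.16, 1.111 and 1.08 for H3K4me1, so that scramble rather than siRNA 2 gave the highest H3K4me3 ratio. A ratio above 1 thus arose for every library, and part of the excess may come from the reference library that both comparisons share.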

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

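All tests of explanations in this part were chosen after the data were seen, and all but the limit of the epithelial list to peaks over 2500 bp from the TSS after their own result was seen. The number of peaks moved in opposite directions with the siRNAs: over scramble it was 1.08 with siRNA 1 and 0.952 with siRNA 2 for H3K4me3, and 1.20 and 0.926 for H3K4me1. Each value is from 1 library, and the difference between the siRNAs was not tested. Peaks on unplaced or alternative sequences, which entered no comparison, numbered 21, 24 and 23 for H3K4me3 and 5, 9 and 5 for H3K4me1 in the scramble, siRNA 1 and siRNA 2 lists.

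More and longer peaks were called in the siRNA 1 libraries, and intervals that cover only counting error in single libraries exclude no explanation, an untested effect of siRNA 1 alone included. For KMT2D knockdown by either siRNA, the peak number with siRNA 2 over scramble, for all peaks and then with at least 1.1 and at least 4 input tags per 10 M, was 0.926 (0.911 to 0.941), 0.878 (0.863 to 0.894) and 1.08 (1.04 to 1.1211) for H3K4me1 and 0.952, 0.929 and 0.938 for H3K4me3. Most of these values go against this explanation. It stays open for H3K4me1, where the covered length was 1.04 over all peaks and 0.961 among those with at least 6 times as many IP as input tags. It also stays open for H3K4me3, where the covered length was 0.994 (0.973 to 1.01, an interval from peak numbers alone). Stronger enrichment of the siRNA 1 IPs stays open too, because its share of IP tags in the 10000 highest-scoring peaks was at least 1.03 times the higher of the others, but these peaks were also longer, and per Mb covered the factor was 0.925 for H3K4me3 and 0.906 for H3K4me1. For the shallower siRNA 1 input, the H3K4me1 peak number over scramble was 1.07 with at least 1.1 input tags per 10 M, down from 1.20, and 0.998 with at least 4, whereas for H3K4me3 it was 1.05 (1.02 to 1.07) and 1.03 (1.01 to 1.06), down from 1.08, and the H3K4me3 covered length went from 1.24 only to 1.23 with at least 1.1.

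Around 50% of the scramble H3K4me1 peaks had no counterpart in a siRNA library. Variation between libraries whatever the siRNA is a candidate source. In lists of equal number the share not shared between the siRNA libraries was 0.947 of that between scramble and siRNA libraries (49.0% against 51.7%). No 2 libraries of a mark had the same siRNA, so this ratio cannot separate such variation from changes particular to each siRNA. Weak peaks near the calling threshold are a further candidate source. The share absent from both siRNA libraries in the highest score decile was 0.0156 of that in the lowest (1.04% against 66.5%). The score is the IP signal of the region and does not measure its distance from that threshold. Median width was 500 bp in the lowest decile and 2888 bp in the highest, so this ratio cannot separate weak peaks from narrow ones. KMT2D knockdown stays open, as the excess over score-matched chance was 1.04 times as high with scramble as the reference (1.16) as with the higher of the siRNA libraries (1.111), too small a gap to decide with 1 library each.

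Less H3K4me1 lay at epithelial and foregut genes in both siRNA libraries. Chance among the lists tested stays open: the share of random lists as low in both libraries, times 2 directions and 27 tests, was 4.86% (2.22 to 9.22%). For a shift of the siRNA 2 peaks to promoters, the median log2 ratio with siRNA 2 went from -0.92 (12 genes, central 95% of random lists -0.73 to 0.30) to -0.84 with only peaks over 2500 bp from the TSS (9 genes, -1 to 0.21, percentile 20.2), and to -0.72 with only peaks within it (7 genes, -1.36 to 0.39, percentile 16.5). Fewer genes and wider random ranges thus went with the end of the call in either part, which neither favours nor excludes the shift. KMT2D knockdown may contribute, with 7 of 12 genes shorter in both siRNA libraries, but this count was made on a list picked for that pattern and does not separate it from chance.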

How the results depend on the processing

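No paired analysis was possible because each group has 1 library and no value comes from a test. Of 129 recomputed values over 22 results and 17 settings, 38 stayed within the counting interval of the reported value (counts of genes or lists within 1.5 times), 89 moved beyond it and 2 changed direction. Of the settings, 5 were chosen after seeing the data: windows around recovered TSSs, lists limited to peaks over or within 2500 bp of the TSS, a minimum input, and a minimum of IP over input. Percentages are given for siRNA 1 and then siRNA 2, and gained peaks as a share of the siRNA library's own list. Fewer or merged peaks and a stricter or looser overlap change these shares by construction; for the other shifts the cause was not tested.

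With at least 50% of a peak required to be covered, of H3K4me3 peaks, 10.1% and 15.1% were absent from the siRNA 1 and siRNA 2 lists, 22.4% and 10.7% were gained and 8.52% were absent from both. Of H3K4me1 peaks, 61.1% and 64.9% were absent from the siRNA 1 and siRNA 2 lists, 72.8% and 66.7% were gained and 48.4% were absent from both. For H3K4me1, the ratio to score-matched chance was 1.121. With gaps of up to 1000 bp counted as shared, of H3K4me3 peaks, 6.27% and 10.3% were absent from the siRNA 1 and siRNA 2 lists, 13.4% and 6.08% were gained and 5.06% were absent from both. For H3K4me3, the ratio to score-matched chance was 1.57. Of H3K4me1 peaks, 35.6% and 41.6% were absent from the siRNA 1 and siRNA 2 lists, 46.6% and 39.1% were gained and 24.5% were absent from both. For H3K4me1, the ratio to score-matched chance was 1.32, and the distal minus promoter difference was 7.24 and 12.7 points. With the higher-scoring 50% of every list, of H3K4me3 peaks, 1.39% and 7.66% were absent from the siRNA 1 and siRNA 2 lists, 9.16% and 3.14% were gained and 1.116% were absent from both. For H3K4me3, the ratio to score-matched chance was 1.75, and the covered length over scramble was 1.28 and 0.969. Of H3K4me1 peaks, 39.3% and 45.3% were absent from the siRNA 1 and siRNA 2 lists, 51.4% and 44.0% were gained and 27.9% were absent from both. For H3K4me1, the ratio to score-matched chance was 1.25, and the covered length over scramble was 1.30 and 1.07, and the distal minus promoter difference was 1.77 and 4.81 points.

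With the higher-scoring 50% of the counted list against all peaks of the other, of H3K4me3 peaks, 0.0113% and 0.0564% were absent from the siRNA 1 and siRNA 2 lists, 0.0209% and 0% were gained and 0.0113% were absent from both. Of H3K4me1 peaks, 29.0% and 33.3% were absent from the siRNA 1 and siRNA 2 lists, 38.0% and 30.5% were gained and 16.6% were absent from both. For H3K4me1, the ratio to score-matched chance was 1.33, and the distal minus promoter difference was 3.56 and 7.88 points. With equal numbers of peaks, of H3K4me3 peaks, 6.71% and 9.43% were absent from the siRNA 1 and siRNA 2 lists, 9.37% and 9.24% were gained and 4.86% were absent from both. For H3K4me3, the ratio to score-matched chance was 1.32. Of H3K4me1 peaks, 50.2% and 51.2% were absent from the siRNA 1 and siRNA 2 lists and 52.6% and 53.02% were gained. For H3K4me1, the covered length over scramble was 1.18 and 1.08. With peaks within 1000 bp merged, of H3K4me3 peaks, 7.44% and 10.8% were absent from the siRNA 1 and siRNA 2 lists, 13.0% and 6.63% were gained and 6.17% were absent from both. Of H3K4me1 peaks, 58.2% and 50.9% were gained. For H3K4me1, the distal minus promoter difference was 13.1 and 19.03 points. The ratio to chance for H3K4me3 in the higher-scoring 50% of the counted list was not computed, since fewer than 5 peaks were expected.

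With a promoter limit of 1000 bp the distal minus promoter difference was -3.52 and 0.0151 points, which turned its direction for siRNA 1, and 409 genes had promoter H3K4me3 in scramble only and 422 in both siRNA libraries only. With 5000 bp the difference for siRNA 2 was 14.8 points. Windows around recovered TSSs gave 25 and 91 such genes. With at least 1.1 input tags per 10 M, the H3K4me1 covered length of siRNA 1 over scramble was 1.21. With at least 6 times as many IP as input tags it was 1.90, and that of siRNA 2 was 0.961, on the other side of 1 from the reported 1.04. The number of lists outside the central 95% of random lists by H3K4me1 in both libraries was 0 with the higher-scoring 50% of peaks, within 50000 bp, only over 2500 bp and only within 2500 bp of the TSS, and 1 with a pseudocount of 100 bp. By promoter H3K4me3 it was 0 in every setting run. The median H3K4me1 peak held 21 to 28 IP tags, and no lists were made at lower depth, so what depth limits was not measured.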

Other observations

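The regions in this part were picked after their values were seen, and no explanation for them was tested. The strongest H3K4me3 peaks lay at the same loci in most libraries. A peak across the CDKN1B and APOLD1 locus, which includes the gene of the cell cycle inhibitor p27, ranked 1 in scramble (chr12:12866818-12882842, 16.02 kb) and siRNA 2 and 2 in siRNA 1. Peaks at SPRY4, an inhibitor of receptor tyrosine kinase signalling, and at TFAP2A-AS1 were among the 5 strongest in all 3 libraries. With siRNA 1 the strongest H3K4me3 peak was intergenic, with TPRG1-AS2 as its nearest gene, at chr3:189110585-189137173 (26.6 kb, 1009.91 IP tags per 10 M). The H3K4me1 peaks ranked 3 and 5 with siRNA 1 lay on the same chromosome and had TPRG1-AS2 and TP63 as their nearest genes, with centres -56766 and -173285 bp from those TSSs.

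The strongest H3K4me1 peak in scramble lay in intron 1 of KIRREL, which encodes a cell adhesion protein (chr1:157966168-157993628, 27.5 kb, 563.39 IP tags per 10 M). It ranked 4 with siRNA 2 (555.5 IP tags per 10 M) and was not among the 5 strongest with siRNA 1.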
